A study of Homo sapiens with 4 samples.

How the data were processed

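RNA-seq libraries labelled as LoVo, a human colorectal adenocarcinoma cell line, were compared, 4 in number. In 2 of them the cells stably carried the pLKO.1 control vector. The other 2 came from cells with a short hairpin RNA against LAMB3, a different hairpin in each library, so the spread within the knockdown group holds the difference between hairpins as well as that between libraries. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

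The values were deposited by the authors as FPKM, fragment counts scaled by transcript length and by mapped fragments, 1 value per gene symbol and library, per the file headers. Trimmomatic 0.36, HISAT2 2.0.5, Cufflinks 2.2.1 and HTSeq 0.9.1 are named per the submitters' processing notes, without their roles. The genome build, the annotation and the strand setting are not given in the sources used here. FPKM carry no read counts, and the values showed no steps of 1 read, so the sequencing depth is unknown and no counting interval can be given. Each library listed 19918 names. Of these, 28 had been turned into dates by a spreadsheet and were left out, with at most 0.156% of any library's sum, and 19890 were kept. No pair of libraries shared any value above 0 for a gene, so no library appeared to be deposited in duplicate.

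The tests had been chosen for read counts and, should the files hold a normalized unit, for a fallback on the log scale, which was the one used. Genes with at least 1 FPKM in at least 2 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The FPKM were not rescaled. The main comparison set both shLAMB3 libraries against both controls. A second model fitted each hairpin separately against the controls and against each other. In it the 2 controls give the only residual degree of freedom, so the spread used for a gene was largely that shared by genes of like level. Each lone hairpin library is assumed to vary like the controls. The same assumption holds for a group reduced to 1 library when libraries were left out in turn.

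Gene lists were tested with camera, which compares a list with the other genes tested, at a preset correlation between genes of 0.01, adjusted over the lists. They were tested again with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes. The 34 lists were basement membrane and laminin chains, integrins and hemidesmosome, focal adhesion and actin, matrix proteases and inhibitors, FOXO target genes, PI3K-AKT-mTOR pathway components, DNA replication and G1/S, G2/M and mitosis, p53 target genes, apoptosis regulators, MYC targets and ribosome biogenesis, cholesterol and fatty acid synthesis, hypoxia and glycolysis, unfolded protein response and ATF4, interferon-stimulated genes, NF-kB targets and cytokines, ERK and immediate-early genes, Wnt targets and intestinal stem cell genes, YAP-TEAD targets, epithelial junction genes, mesenchymal and EMT genes, enterocyte differentiation, goblet and enteroendocrine, keratins and squamous genes, NRF2 and oxidative stress, heat shock, autophagy and lysosome, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, and markers of fibroblasts, leukocytes and endothelial cells. A list needed 3 tested members. The groups, the lists, the comparisons, the fallback test, its threshold and the rule for named genes were fixed before the data were examined.

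The rule names LAMB3 first. It then takes the 12 largest rises and the 12 largest falls that pass the threshold with a mean of at least 5 FPKM and both shLAMB3 libraries on the same side of both controls. Where fewer than 5 genes pass in a direction, it takes the 5 with the smallest p under the same conditions, which are said not to pass. It also takes the up to 4 members of each list with the smallest p, the 5 largest rises and falls past the threshold in each hairpin comparison, and AKT1, FOXO3, FOXO4, BRD2 and ELK4 whatever their values. Y-linked genes and XIST are never named. Any other gene is said to have been chosen after its values were seen. Some items were withheld and are not reported here.

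Because control 1 differed from the other libraries along GC content and transcript length, an alternative was added after seeing the data. In each library the part of the deviation from the gene mean that follows GC content and log length was removed, with natural splines of 5 degrees of freedom for each. GC content and length came from the longest protein-coding transcript of GENCODE release 29. Symbols in the files matched a transcript for 19117 of 19890 genes, 357 of them through an older or newer symbol, and 10397 of the 10450 genes tested had both values. The matching through older symbols was extended after the first counts of calls had been seen, and the counts with direct matching alone are given beside the others. This removal would also take away true effects that follow GC content or length.

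Also added after seeing the data were median-of-ratios scaling, upper quartile scaling, quantile normalization, a filter of 5 FPKM, library weights, the hairpin fits at a pseudocount of 0.1, and combinations of the trend removal with the replicate block or without control 1. The alternatives written down before the data were seen were no filter beyond a value above 0, a pseudocount of 0.1, a minimum change of 2-fold, the replicate number as a block, the estimated correlation, fry, and each library left out in turn.

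The code was tested on simulated data for 10397 genes, 200 of them changed. For knockdown against control at the spread of the deposited values, 25.4%, 88.1% and 100% of changes of 1, 2 and 3 log2 units were called, with 5 unchanged genes called. At the smaller spread left after the trend was removed, 95.5%, 100% and 100% were called, with 21 unchanged genes called, which is more than the threshold allows for. With the trend of each library added to the simulated values the shares were 14.9%, 95.5% and 100% with 3 unchanged genes called, and after its removal 97.0%, 100% and 100% with 22 unchanged genes called. A simulated shift of 0.8 in the hypoxia and glycolysis list gave an adjusted p of 6.23e-22 at the preset correlation and 0.219 with an estimated correlation, and 0 of 27 lists that share no gene with it were called. In 20 simulations without any change, 2 lists were called in total. For the lists, genes were simulated independently of each other and without the GC and length trend. These counts therefore do not show how often unchanged lists are called in the data, where genes move together. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for reading the files and for the plots.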

Results

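Gene expression was measured by RNA-seq in 4 libraries labelled as LoVo cells, to find which genes differ after knockdown of LAMB3, the gene of the laminin beta-3 chain. This chain is part of laminin-332, a basement membrane protein that anchors epithelial cells. There were 2 control libraries and 2 shLAMB3 libraries, the first with hairpin 1 and the second with hairpin 2. The FPKM summed to 429602 and 318544 in the controls and to 327999 and 320308 in the shLAMB3 libraries. Between 9746 and 10460 genes reached 1 FPKM per library. The read depth behind the values is unknown.

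EPCAM, CDH1 and a set of intestinal genes were close to the floor in all 4 libraries, while VIM and keratin genes were high. EPCAM, an epithelial adhesion gene, lay between 0.239 and 0.635 FPKM, and CDH1, the gene of E-cadherin, between 0 and 0.0143. The intestinal genes CDH17, VIL1, CDX2, CEACAM5 and KRT20 were listed at 0 in each library. VIM, the gene of the mesenchymal filament vimentin, ranged from 1260 to 1700 FPKM, and the epithelial keratin genes KRT8 and KRT18 from 176 to 459. LAMA3, the gene of a laminin alpha chain, lay between 0.0563 and 0.121 FPKM. Apart from KRT8 and KRT18, the genes in this paragraph were chosen after their values were seen.

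Control 1 stood apart from the other 3 libraries. Its Spearman correlations with them across genes were 0.909, 0.913 and 0.909, against 0.977 to 0.982 among the others, where genes are not independent replicates. The 20% of genes with the lowest GC content had a median log2 difference of -0.84 between control 1 and the mean of the others, and the 20% with the highest 0.65. The 20% with the shortest transcripts had a median of 0.49 and the 20% with the longest -0.76. GC content and length together explained 76%, 64.3% and 61.5% of the variance of the difference between control 1 and each other library, and 5%, 4.23% and 1.31% for the pairs without it. With this trend removed, the correlations of control 1 were 0.959 to 0.975 and those among the others 0.978 to 0.983. Calls below are therefore given as deposited first and then with the trend removed, an alternative chosen after seeing the data.

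**Figure D1:**
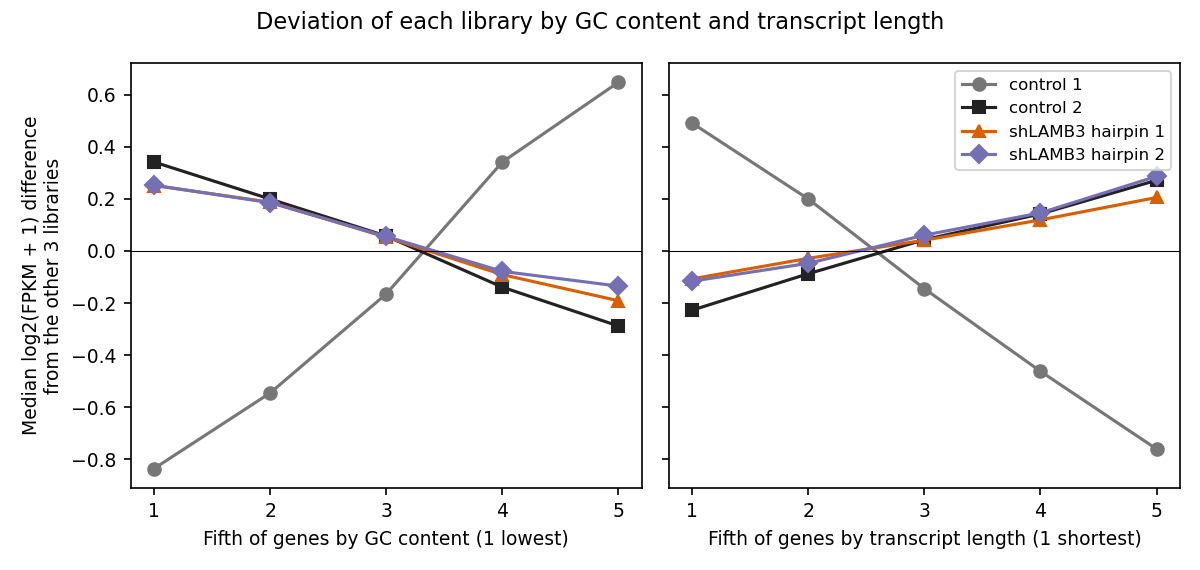
Median difference in log2(FPKM + 1) between each library and the mean of the other 3 libraries (y axis), for genes in 5 equal groups by GC content (left) and by transcript length (right). Each line is 1 library; control 1 runs from -0.84 to 0.65 with GC content and from 0.49 to -0.76 with length, against the other libraries, whose slopes are the opposite partly because control 1 is in the mean they are compared with.

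LAMB3 transcript was lower in both knockdown libraries. It measured 169 and 114 FPKM in the controls, 25.8 with hairpin 1 and 21 with hairpin 2, which left 18.2% and 14.8% of the control mean. Against control 2 alone 22.6% and 18.4% were left. The log2 difference was -2.53 (SE 0.35, n = 2 against 2), lower in 2 of 2 libraries, and did not pass the test as deposited (limma adjusted p = 0.129). With the GC and length trend removed LAMB3 fell by 2.41 (SE 0.18, adjusted p = 0.00511). Over 17 alternatives the adjusted p ran from 6.42e-05 to 1, the log2 difference from -2.81 to -2.24, and LAMB3 was called in 8. Leaving out control 2 brought the call as well (adjusted p = 0.0141), and leaving out control 1 did not (0.22). In the annotation of build GRCh38, release 29 of GENCODE, LAMB3 lies on the minus strand of chromosome 1 from 209614870 to 209652466; the build of the authors is not given in the sources used here.

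The comparison of both shLAMB3 libraries with both controls asked which other genes differ after knockdown. Among genes with a mean of at least 5 FPKM and both knockdown libraries on the same side of both controls, the smallest p upward belonged to STC1, the gene of the secreted glycoprotein stanniocalcin-1, with 7.70 and 13.4 FPKM in the controls and 85.1 and 146 in the knockdown, a log2 difference of 3.33 (SE 0.40, adjusted p = 0.0727, and 1.35e-09 to 0.682 over 17 alternatives, with a call in 11). ANGPTL4, a secreted inhibitor of lipoprotein lipase, went from 8.95 and 4.67 to 33.0 and 30 FPKM (2.11, SE 0.38, adjusted p = 0.382), and NDRG1, a gene induced by low oxygen, from 28.0 and 21.6 to 78.7 and 157 (2.13, SE 0.39, adjusted p = 0.382). ERRFI1, a feedback inhibitor of EGFR, measured 37.0 and 67.9 FPKM in the controls and 204 and 197 in the knockdown (1.98, SE 0.37). DDIT4, an inhibitor of mTORC1, measured 29 and 19.4 against 66.8 and 110 (1.81, SE 0.38). Downward and after LAMB3, the smallest p among such genes belonged to CD82, a tetraspanin, with 16.4 and 10.9 FPKM in the controls and 5.06 and 1.66 in the knockdown, and to CSF2, the gene of the cytokine GM-CSF, with 20.6 and 13.2 against 7.19 and 4.54. S100A3 (24.9 and 11.6 against 6.40 and 5.48) and TINAGL1, a matrix gene (68.3 and 37.0 against 20 and 21.4), followed, and the adjusted p of these 4 genes was 0.901.

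None of these genes passed as deposited: limma called 0 of 10450 genes, with a lowest adjusted p of 0.0727, while 235 genes had an unadjusted p under 0.05, 177 higher and 58 lower. Other settings of the same tool are the only other counts, as no count-based tool can take FPKM. In 1905 genes (18.2%) both knockdown libraries lay above both controls and in 1335 (12.8%) below both, where chance gives 16.7% in each direction. Leaving out control 2 raised the calls to 2883 higher and 1741 lower, including the 10 genes named by smallest p, and leaves control 1 with its GC and length trend as the only control. Leaving out control 1 gave 0 higher and 1 lower, SPANXA1, a member of a family of near-identical X-linked genes whose reads cannot be told apart with certainty, at 7.86 and 77.8 FPKM in the controls and 5.81 and 5.96 in the knockdown (adjusted p = 0.0326, and 0.0116 to 1 over 17 alternatives). Leaving out hairpin 1 gave 1 higher, STC1 (adjusted p = 0.00645), and leaving out hairpin 2 gave 1 higher, BOLA2B (0.00161). SPANXA1 was chosen after its values were seen.

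**Figure D2:**
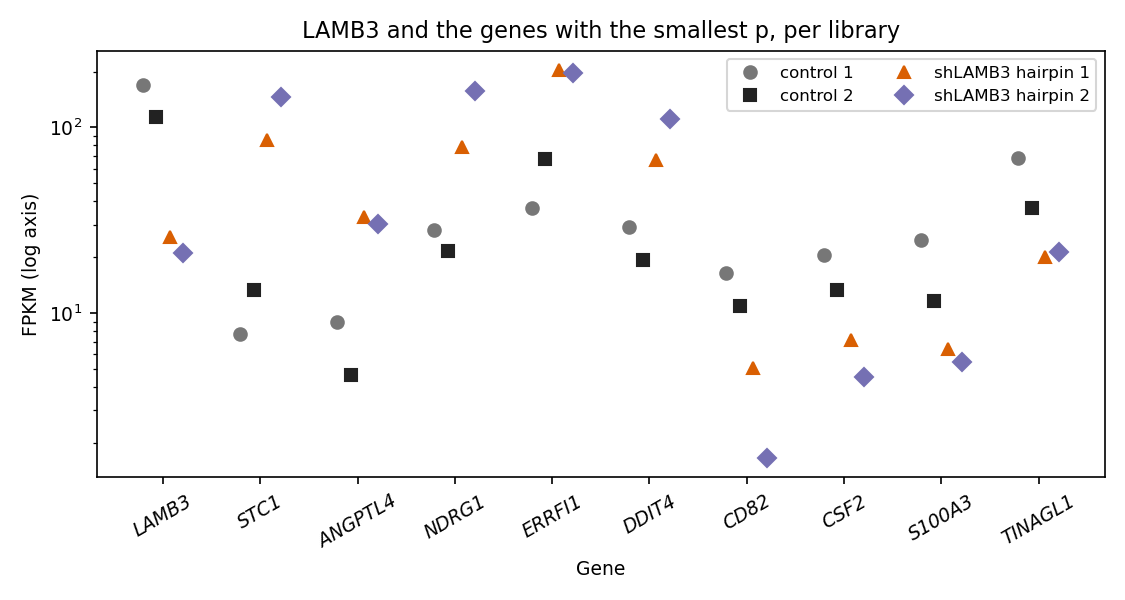
FPKM on a log axis for LAMB3 and the genes with the smallest p in each direction among those with a mean of at least 5 FPKM and both knockdown libraries on the same side of both controls, 1 point per library, by control and hairpin. STC1 measured 7.70 and 13.4 FPKM in the controls and 85.1 and 146 in the shLAMB3 libraries, and no gene shown passed the test as deposited.

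With the GC and length trend removed, 10 genes rose and 2 fell of 10397 tested, with adjusted p between 0.00458 and 0.0497. ANGPTL4 rose by 2.41 log2 units (SE 0.16), STC1 by 3.08 (SE 0.25), NDRG1 by 2.27 (SE 0.28), DDIT4 by 2.08 (SE 0.24) and ERRFI1 by 1.77 (SE 0.18). C10orf10, also known as DEPP1 and a target of FOXO factors, rose by 2.43 (SE 0.20), from 0.791 and 0.397 FPKM to 5.39 and 7.40. GDF15, a stress-induced cytokine, rose by 1.51 (SE 0.19), and PTGS2, the gene of cyclooxygenase-2, by 1.29 (SE 0.17). Chosen after their values were seen, CA9, a carbonic anhydrase induced by low oxygen, rose by 1.74 (SE 0.16) from 7.68 and 3.60 to 15.3 and 17.1 FPKM, the readthrough PPAN-P2RY11 rose by 1.60 and the readthrough HSPE1-MOB4 fell by 1.37. Both readthroughs overlap other genes, so their values are uncertain, and LAMB3 was the other gene that fell. Over the alternatives, the adjusted p of each of these 12 genes went up to 1 or, for STC1, 0.682, and down to between 1.35e-09 and 0.0308. GDF15, PTGS2 and HSPE1-MOB4 passed at 0.0497. With symbols matched directly alone the counts were 7 rises and 1 fall of 10166 genes. GDF15, PTGS2 and HSPE1-MOB4 were not called there, and C10orf10, matched only through its newer symbol, was not among the genes tested. When control 1 was left out as well, 0 genes rose and 1 fell, SPANXA1 (adjusted p = 0.0116).

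The list of genes induced by low oxygen and genes of glycolysis was higher in the knockdown, less so for the glycolytic enzymes. Of 37 members tested, 26 were higher in both knockdown libraries than in both controls and 0 lower, with a median log2 difference of 0.84 (camera adjusted p = 3.32e-13, and 0.673 with an estimated correlation). With an estimated correlation camera also missed a simulated shift of 0.8 in this list (adjusted p = 0.219). A missing call with it, here and for the lists below, therefore does not show that a list is unchanged. With fry, which was not run on simulated data, 0 lists were called as deposited or with the trend removed. Its adjusted p for the hypoxia list was 0.536 and 0.306. In a split made after the values were seen, and not tested, 5 of 14 genes of glycolytic enzymes and lactate dehydrogenase were higher in both and 9 overlapped the controls, with a median of 0.088, against 21 of 23 other members, with a median of 0.97. HK2, the gene of the glycolytic enzyme hexokinase 2, measured 8.17 and 18.3 FPKM in the controls and 42.1 and 46.5 in the knockdown, and MXI1, a MYC antagonist, 2.93 and 4.46 against 10.5 and 15.4. ENO1, the gene of the glycolytic enzyme enolase 1 and chosen after its values were seen, measured 1444 and 818 FPKM against 899 and 843. The low median of the enzymes rested partly on control 1. Without it the log2 differences of ALDOA, TPI1 and GPI moved from -0.075, -0.030 and 0.079 to 0.45, 0.41 and 0.40. Those of ENO1, PKM and PFKP moved from -0.32, -0.37 and -0.34 to 0.090, 0.023 and 0.066. HK2 went the other way, from 1.77 to 1.23, and PGK1 and LDHA did so slightly. These genes too were picked after their values were seen. No member passed over all genes tested as deposited, and 5 rose adjusted over the list alone. With the trend removed the median was 0.64 (camera adjusted p = 2.14e-22, and 0.693 with an estimated correlation), the medians of the 14 and the 23 were 0.23 and 0.81, ANGPTL4, NDRG1 and CA9 rose over all genes tested and 21 members rose adjusted over the list alone. The list was called in 17 of 17 alternatives at the preset correlation, with adjusted p from 6.32e-28 to 0.0316. Against control 2 alone its median was 0.53 for hairpin 1 and 0.77 for hairpin 2.

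FOXO target genes were higher as well. FOXO factors are transcription factors that AKT keeps out of the nucleus. Of 22 members tested, 13 were higher in both knockdown libraries and 0 lower, with a median of 0.49 (camera adjusted p = 4.72e-08, and 0.673 with an estimated correlation). Beside C10orf10, TXNIP, an inhibitor of thioredoxin and glucose uptake, measured 4.88 and 5.68 FPKM against 14.2 and 23.0, and CCNG2, a cyclin linked to arrest, 1.56 and 3.19 against 6.36 and 11.5. MXI1 belongs to this list and to the hypoxia list. No member passed over all genes tested as deposited and 4 rose adjusted over the list alone. After removal of the trend C10orf10 rose, 7 members rose adjusted over the list alone, and the median was 0.40 (camera adjusted p = 3.63e-08, 0.816 with an estimated correlation, and 4.36e-13 to 0.00419 over 17 alternatives at the preset correlation). The median was 0.19 without control 1 and 0.82 without control 2, as deposited. Against control 2 alone it was 0.13 for hairpin 1 and 0.48 for hairpin 2, so the rise was small with hairpin 1.

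The genes around AKT and FOXO themselves, with BRD2 and ELK4, did not pass. AKT1 measured 66.1 and 42.1 FPKM in the controls and 33.7 and 41.3 in the knockdown, FOXO3 1.07 and 3.22 against 3.65 and 4.47, and FOXO4, below the filter, 0.541 and 0.590 against 0.992 and 1.33. BRD2, a reader of acetylated histones, measured 59.4 and 53 against 41.2 and 46.5, and the transcription factor gene ELK4 1.59 and 4.29 against 3.86 and 3.64; its log2 difference was 0.36 as deposited and -0.17 with the trend removed. The PI3K-AKT-mTOR pathway components had a median of 0.18 over 31 members (camera adjusted p = 0.769, 0.959 with an estimated correlation), with RICTOR at 1.95 and 8.96 FPKM against 9.48 and 12.5 and EGFR at 3.34 and 20.9 against 19.5 and 24.1. The median turned to -0.071 with the trend removed.

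Genes of mitosis and of DNA replication were lower as lists relative to the other genes, which is the comparison camera makes. The median log2 difference over all genes tested was 0.077 as deposited. Of 51 members of G2/M and mitosis, 22 were lower in both knockdown libraries and 0 higher, with a median of -0.019 (camera adjusted p = 0.00775, 0.673 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, measured 264 and 145 FPKM against 126 and 104, the mitotic kinase gene PLK1 96.9 and 60.7 against 44.8 and 46.0, CDCA3 42.9 and 29.3 against 20.9 and 17.0, and BIRC5, the gene of survivin, 42.7 and 33.6 against 23.7 and 26.2. Of 47 members of DNA replication and G1/S, 18 were lower in both and 1 higher, with a median of -0.11 (camera adjusted p = 0.00832, 0.673 with an estimated correlation); thymidine kinase gene TK1 measured 150 and 75.6 against 65.5 and 56.8, and MCM5, a part of the replicative helicase, 71.9 and 43.3 against 38 and 35.1. No member of either list passed over all genes or adjusted over the list alone, as deposited or with the trend removed. After its removal the medians were -0.26 for mitosis (adjusted p = 7.13e-09, 0.503 with an estimated correlation) and -0.18 for replication (0.000655, 0.698 with an estimated correlation), and over 17 alternatives the adjusted p ran from 7.56e-18 to 0.986 and from 1.05e-05 to 0.433. Without control 1 the medians were -0.33 and -0.16; without control 2 neither list was called (adjusted p = 0.986 with a median of 0.13, and 0.433 with a median of -0.0042), nor without hairpin 2 (0.0549 and 0.0953, with medians of -0.084 and -0.041). Without hairpin 1 the median of mitosis was -0.0029. Quantile normalization ended both calls (0.23 and 0.203) and a filter of 5 FPKM that of replication (0.0553). Upper quartile scaling turned the median of mitosis to 0.081 with the test still downward, while the median over all genes was then 0.16.

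**Figure D3:**
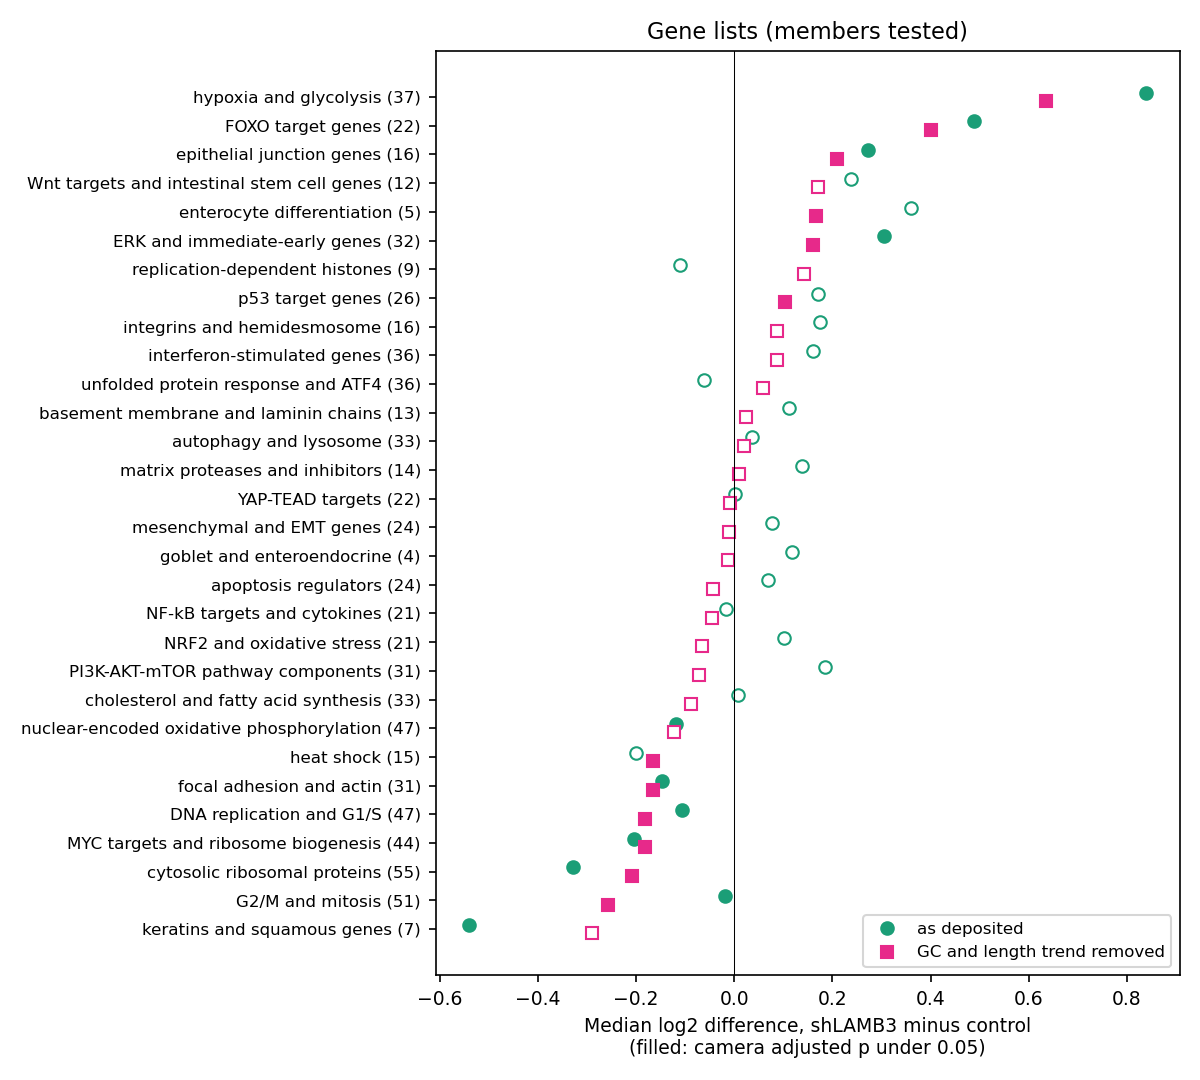
Median log2 difference between the shLAMB3 and control libraries (x axis) of each of the 30 tested gene lists (y axis, members tested in brackets), as deposited (circles) and with the GC and length trend removed (squares); filled symbols mark camera adjusted p under 0.05 at the preset correlation, and 0 lists pass with an estimated correlation. That setting also missed a simulated shift of 0.8 in the hypoxia list. With fry, which was not run on simulated data, 0 lists pass as well. Hypoxia and glycolysis had the highest median in both, 0.84 and 0.64; the oxidative phosphorylation list turns upward with quantile normalization and, like the ribosomal proteins, without control 1.

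Genes of protein synthesis and respiration were lower as deposited, and their calls ended when control 1 was left out of the deposited values. The 55 cytosolic ribosomal proteins had a median of -0.33, with 9 lower in both knockdown libraries and 1 higher (camera adjusted p = 4.72e-08, 0.798 with an estimated correlation); RPL35 measured 3824 and 1914 FPKM against 1861 and 1625. Without control 1 their median was 0.033 (0.568, and 0.381 with the trend removed as well), without control 2 it was -0.73, and quantile normalization ended the call (0.676). The 44 MYC targets and ribosome biogenesis genes had a median of -0.20 (0.00612, 0.673 with an estimated correlation), with the nucleolar gene MRTO4 at 53 and 30.3 against 26.8 and 20.6; the call ended without control 1 (0.0794, median -0.11), control 2 (0.0502, median -0.32) or hairpin 2 (0.301, median -0.084) and with quantile normalization (0.644), and it was made without control 1 when the trend was removed as well (0.0326). The 47 nuclear-encoded oxidative phosphorylation genes had a median of -0.12 (0.00612, 0.886 with an estimated correlation), with ATP5D, a subunit of ATP synthase, at 185 and 77.9 against 64.5 and 76.3. Only 6 of the 47 were lower in both knockdown libraries and 3 higher, where 12.8% and 18.2% of all genes tested were. Their direction turned without control 1 (0.0787, median 0.093, and 0.585 with the trend removed as well) and with quantile normalization (0.676), the median was -0.38 without control 2 and -0.19 without hairpin 1, and the call ended without hairpin 2 (0.0746) and with the trend removed (0.0534, of a range from 2.64e-05 to 0.676). The ribosomal proteins kept, without the trend, a median of -0.21 (1.13e-05, of 1.43e-14 to 0.676, and 0.852 with an estimated correlation) and the MYC targets one of -0.18 (0.0173, of 7.24e-05 to 0.644, and 0.852 with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone. The 13 mitochondrially encoded genes were not among the listed genes.

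Among genes of adhesion and matrix, focal adhesion and actin genes were lower as a list, and integrins, laminins and proteases were not called. Of 31 focal adhesion and actin genes 8 were lower in both knockdown libraries and 2 higher, with a median of -0.15 (camera adjusted p = 0.00799, 0.673 with an estimated correlation); the adaptor gene BCAR1 measured 22.2 and 13.1 FPKM against 9 and 10.4. With the trend removed the median was -0.17 (0.0132, of 0.00213 to 0.23, and 0.816 with an estimated correlation). As deposited it was -0.25 without control 2, and the call ended without control 1 (0.107, median -0.045; with the trend removed as well it was made, at 0.0411), with quantile normalization (0.23) and with a filter of 5 FPKM (0.0553). The 16 integrins and hemidesmosome genes had a median of 0.17 (0.871, 0.959 with an estimated correlation), with the laminin and collagen receptor genes ITGA2 at 6.41 and 29.6 against 36.0 and 54.7 and ITGA6 at 14.4 and 48.4 against 49.0 and 75.5, and BCAM, a laminin receptor, at 7.67 and 4.43 against 2.43 and 2.13; they were called upward without hairpin 1 (0.0332, of 0.0332 to 0.999). The 13 basement membrane and laminin chains had a median of 0.11 while the test pointed down (0.896, 0.959 with an estimated correlation). The 14 matrix proteases and inhibitors had a median of 0.14 (0.896, 0.959 with an estimated correlation); MMP1, a collagenase, rose adjusted over the list alone, from 0.485 and 0.595 to 3.77 and 2.42, and PLAU, the gene of urokinase, measured 39.0 and 31.7 against 14.1 and 18.0.

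ERK and immediate-early genes were higher as a list at the preset correlation. Of 32 members 11 were higher in both knockdown libraries and 2 lower, with a median of 0.31 (camera adjusted p = 0.0446, 0.673 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone as deposited. The phosphatase genes DUSP1 and DUSP5 measured 18.0 and 15.3 FPKM against 52.4 and 35.9 and 34.3 and 36.3 against 73.4 and 79.2, AREG, an EGFR ligand, 21.6 and 19.9 against 40.7 and 62.9, while FOSL1, a part of AP-1, measured 353 and 193 against 116 and 138. The median was 0.16 and the adjusted p 0.00658 with the trend removed, of a range from 0.000752 to 0.433, and 0.816 with an estimated correlation; 4 members then rose and 2 fell adjusted over the list alone. Among the settings that ended the call were those without control 1 (0.113, median 0.068, and 0.0962 with the trend removed as well), control 2 (0.433, median 0.52) or hairpin 2 (0.221, median 0.18), with median-of-ratios scaling (0.053) and at a pseudocount of 0.1 (0.0514). NF-kB targets and cytokines moved both ways over 21 members, with a median of -0.018 (0.313, 0.673 with an estimated correlation). PTGS2, at 0.885 and 3.03 against 7.84 and 8.07, rose adjusted over that list alone, while the chemokine gene CXCL1 measured 11.7 and 11.2 against 5.67 and 3.34.

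Epithelial junction genes were higher and keratins lower as lists. Of 16 junction genes 4 were higher in both knockdown libraries and 0 lower, with a median of 0.27 (camera adjusted p = 0.0428, 0.673 with an estimated correlation); DSP, the gene of desmoplakin, measured 3.28 and 8.71 FPKM against 10.6 and 13.1 and CLDN7 5.14 and 2.98 against 6.28 and 9.58. With the trend removed the median was 0.21 (0.0371, of 0.0106 to 0.474, and 0.816 with an estimated correlation). The call ended without control 1 (0.474, median 0.086, and 0.264 with the trend removed as well), control 2 (0.114, median 0.56) or hairpin 2 (0.216), without the filter (0.284) and with quantile normalization (0.0866). The 7 keratins and squamous genes had a median of -0.54 (0.00724, 0.743 with an estimated correlation), with KRT7 at 278 and 140 against 129 and 108. Their median was -1.01 without control 2, and that call ended without control 1 (0.999, median -0.069, and 0.698 with the trend removed as well) or hairpin 2 (0.194), with the trend removed (0.29, of 0.000441 to 0.999), with quantile normalization (0.23) and without the filter (0.556). No member of either list passed over all genes or adjusted over the list alone as deposited. The 24 mesenchymal and EMT genes had a median of 0.077 (0.943, 0.959 with an estimated correlation); INHBA, an activin subunit gene, rose adjusted over that list alone, from 0.984 and 2.36 to 7.73 and 6.10.

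The remaining lists were not called as deposited, and no member passed over all genes tested. Medians were 0.17 for 26 p53 target genes (camera adjusted p = 0.706, 0.886 with an estimated correlation), 0.069 for 24 apoptosis regulators (0.859, 0.959), 0.16 for 36 interferon-stimulated genes (0.55, 0.959), 0.24 for 12 Wnt targets and intestinal stem cell genes (0.871, 0.959), 0.36 for 5 enterocyte differentiation genes (0.183, 0.673), -0.20 for 15 heat shock genes (0.241, 0.772) and -0.11 for 9 replication-dependent histones (0.117, 0.673), the second value in each bracket being the adjusted p with an estimated correlation. The median and the test differed in sign for 33 cholesterol and fatty acid synthesis genes (0.0066, downward, 0.313 and 0.673), 22 YAP-TEAD targets (0.0018, downward, 0.781 and 0.959), 21 NRF2 and oxidative stress genes (0.10, downward, 0.958 and 0.959), 33 autophagy and lysosome genes (0.037, downward, 0.706 and 0.959) and 4 goblet and enteroendocrine genes (0.12 with a mean of -0.051, downward, 0.613 and 0.959). Such a difference in sign can arise because camera compares a list with the other genes, and the median over all genes tested was 0.077. The 36 unfolded protein response and ATF4 genes had a median of -0.062, a mean of 0.096 and a test downward (0.935 and 0.959), and DDIT4 rose adjusted over that list alone. MDM2, a p53 target, measured 4.52 and 8.37 FPKM against 13.8 and 11.9, and MCL1, an inhibitor of apoptosis, 59.1 and 123 against 187 and 165.

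Some of these lists were called under a few of the settings. The p53 targets (adjusted p = 0.032, of 0.0285 to 0.978, and 0.816 with an estimated correlation) and the enterocyte genes (0.0491, of 0.033 to 0.641, and 0.816) were higher with the trend removed and the heat shock genes lower (0.0491, of 0.0482 to 0.882, and 0.852). YAP-TEAD targets were lower without control 1 (0.0117, of 0.0117 to 0.906, and 0.014 with the trend removed as well), interferon-stimulated genes higher without hairpin 1 (0.0475, of 0.0475 to 0.829), goblet and enteroendocrine genes lower without hairpin 2 (0.00269, of 0.00269 to 0.999), and histones lower without hairpin 1 (0.0316, of 0.0316 to 0.999) and without the filter (0.0352). The estimated correlation was not run for these last settings.

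The directions of the 19 lists not called as deposited were not stable. With the trend removed the medians of PI3K-AKT-mTOR components, apoptosis regulators (-0.043), cholesterol and fatty acid synthesis (-0.088), YAP-TEAD targets (-0.0091), mesenchymal and EMT genes (-0.011), goblet and enteroendocrine genes (-0.013) and NRF2 and oxidative stress genes (-0.066) turned negative, and those of the unfolded protein response and ATF4 (0.059) and histones (0.14) positive; integrins had 0.088, laminin chains 0.023 and matrix proteases 0.0087. Without control 1 the test turned for 11 of the 19 lists, among them Wnt targets (median 0.011), integrins (0.047), matrix proteases (0.025), mesenchymal and EMT genes (-0.081) and PI3K-AKT-mTOR components (-0.026), and the median of interferon-stimulated genes was -0.057. The test turned for 3 lists without control 2, 4 without hairpin 1 and 7 without hairpin 2.

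Lists of cell types other than epithelial had 2 tested members each and were not tested. Fibroblast markers COL6A1 and COL6A2 measured 43.9 and 27.8 FPKM against 14.3 and 21.4 and 24.1 and 12.1 against 9.10 and 8.20, and both fell adjusted over the list alone. The leukocyte marker LCP1 measured 15.9 and 23.0 against 32.5 and 56.9 and rose adjusted over the list alone, CD68 72.7 and 42.3 against 61.8 and 58.2, and the endothelial markers ESAM 64.8 and 39.9 against 44.5 and 38.3 and ROBO4 5.71 and 3.67 against 3.70 and 2.45. Of 43 markers of these 3 cell types, 6, 6, 7 and 7 reached 1 FPKM in the 4 libraries.

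Each hairpin was then compared with the controls on its own, as 1 library whose spread is taken from the 2 controls and largely shared across genes of like level. The counts therefore describe that library and establish no effect of the hairpin. With hairpin 1 only BOLA2B passed, upward: it measured 3.52 and 2.48 FPKM in the controls, 68.3 with hairpin 1 and 6.16 with hairpin 2 (log2 4.13, SE 0.80, adjusted p = 0.00254). BOLA2B shares its reads with a near-identical copy, BOLA2, so its value is uncertain. With hairpin 2 only STC1 passed, upward (log2 3.71, SE 0.75, adjusted p = 0.00696). At an unadjusted p under 0.05 there were 43 genes for hairpin 1, 30 higher and 13 lower, and 74 for hairpin 2, 53 higher and 21 lower. After the trend was removed, 60 genes were called higher and 45 lower with hairpin 1, and 127 higher and 53 lower with hairpin 2. BOLA2B and STC1 were called in 7 of 8 alternatives each, with adjusted p from 3.69e-29 to 0.45 and from 1.44e-20 to 0.42, and without the filter 0 genes were called for either hairpin.

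Between the hairpins, IL11, the gene of the cytokine interleukin-11, was the gene past the threshold of the fit. IL11 measured 52.4 and 40.9 FPKM in the controls, 110 with hairpin 1 and 6.05 with hairpin 2, a log2 difference of -3.98 (SE 0.86, adjusted p = 0.0405). Each hairpin is 1 library and the spread comes from the 2 controls alone, control 1 with its trend among them, largely shared across genes of like level. These values therefore show a difference between 2 libraries and establish none between hairpins. No gene was higher with hairpin 2, and 18 genes had an unadjusted p under 0.05, 11 higher and 7 lower. IL11 was called in 6 of 8 alternatives, with adjusted p from 1.61e-20 to 0.506, and not with median-of-ratios scaling or without the filter. After removal of the trend 27 genes were higher and 24 lower with hairpin 2 than with hairpin 1.

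The log2 differences of the 2 hairpins from the shared controls correlated across 10450 genes with r = 0.746 and a covariance of 0.13. Unchanged hairpin libraries simulated against the same controls gave 0.749 and 0.134 over 100 simulations, so as deposited the covariance differed from that of the shared controls by -0.0035. With the trend removed r was 0.605 and the covariance 0.0667, against 0.414 and 0.0312 in simulation, a difference of 0.0355. In the same values 37 genes were called higher and 7 lower with both hairpins, where independent lists would share 0.733 and 0.229. Both hairpins use the same 2 controls, which raises the overlap above that of independent lists, and simulated unchanged libraries shared 0 calls, so neither number is a measure of the overlap without a shared effect. The correlation as deposited was 0.551 without control 1 and 0.912 without control 2. As deposited, the hairpins shared 0 calls. The 2 controls cannot be split between the hairpins. Genes of the hypoxia and glycolysis list had medians of 0.51 with hairpin 1 and 0.71 with hairpin 2, FOXO targets 0.25 and 0.60, and mitotic genes -0.28 and -0.23, with the trend removed.

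**Figure D4:**
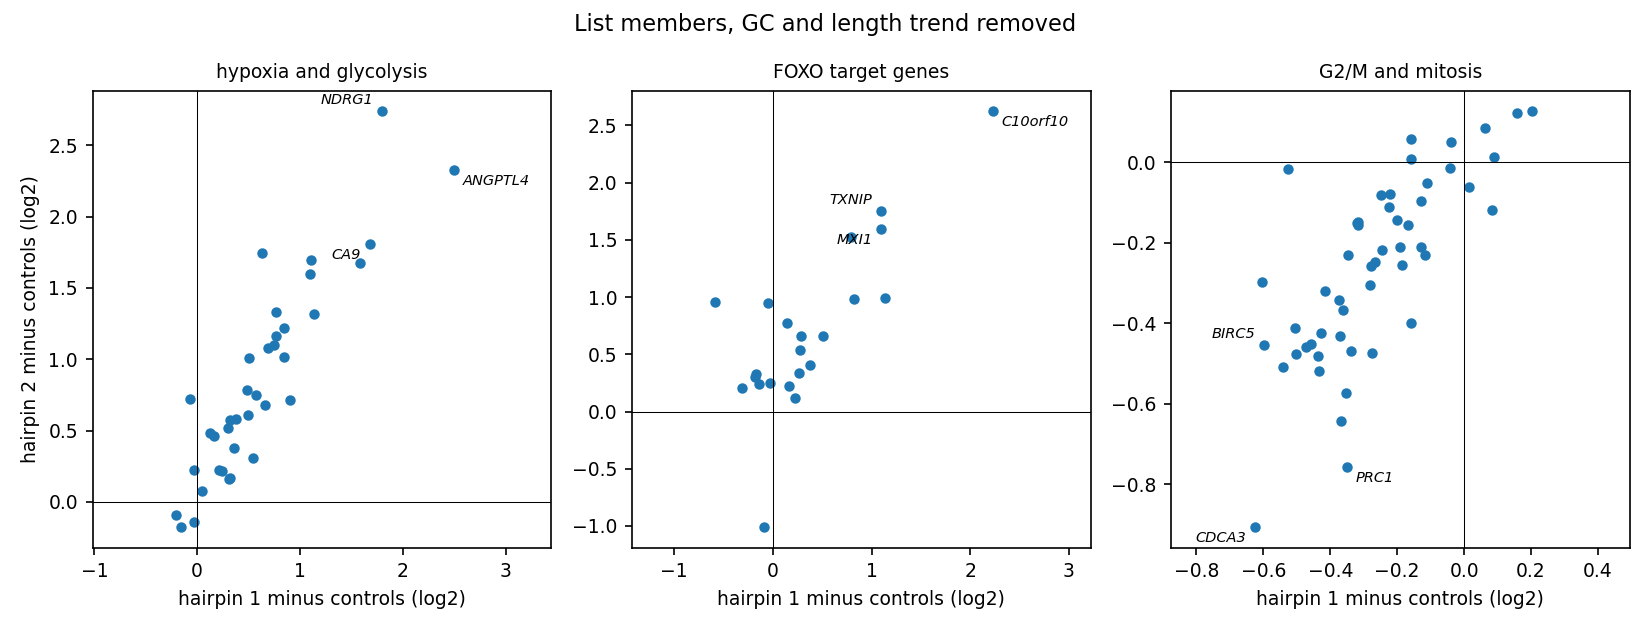
Log2 difference from the controls of each member of 3 gene lists with hairpin 1 (x axis) and hairpin 2 (y axis), with the GC and length trend removed; each point is 1 gene, the axes differ between panels, and both hairpins share the same 2 controls. Medians are 0.51 and 0.71 for hypoxia and glycolysis, 0.25 and 0.60 for FOXO targets, and -0.28 and -0.23 for G2/M and mitosis.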

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

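Of the tests in this part, those on library bias, labels, other cell types, the hairpins and the 6 colon genes were chosen only after the result was seen, while the test between hairpins and the count of housekeeping genes at 0 were not.

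IL11 stood out between the libraries of the 2 hairpins. Its log2 difference was -3.98 for hairpin 2 minus hairpin 1, with 110 FPKM for hairpin 1, 6.05 for hairpin 2 and 52.4 and 40.9 in the controls. Each hairpin has 1 library and the spread came from the controls alone, so no difference between hairpins is established, and the adjusted p went up to 0.506 over the alternatives.

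Control 1 stood apart from the other 3 libraries. A knockdown library labelled as control is argued against by LAMB3, which was 7.24 times the mean of the shLAMB3 libraries in control 1. RNA of other cell types in control 1 stays open. The markers of fibroblasts, leukocytes and endothelial cells reaching 1 FPKM in it, minus the most in another library, came to -1. However, 5 of the 8 that reached 1 FPKM in any library, among them COL6A1 and ESAM, were highest in control 1. These levels were taken as deposited, without allowing for the GC and length trend of control 1, so that count decides nothing. A GC content and length bias in control 1 is a candidate explanation, as both together explained 71.5% of the variance of its difference from the other 3. Whether such a bias arose in library preparation, in RNA quality or in the estimation of FPKM was not tested, and no biological explanation was tested.

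The hypoxia and glycolysis list was higher in both shLAMB3 libraries. As deposited the rise was smaller for the glycolytic enzymes, in a split made after the values were seen and not tested, and that gap rested partly on control 1. GC content and length bias in control 1 does not account for the whole rise of the list, since its median log2 difference was 0.635 after the trend was removed. An off-target effect of 1 hairpin stays open: the smaller of the hairpins' medians against control 2 was 0.526, but both medians share that control, which fixes part of their likeness. An effect of LAMB3 knockdown stays open as well and was not tested apart from these. Denser or older cultures in the knockdown arm, or an effect of any hairpin beside the control vector, could give the same pattern. With an estimated correlation between genes the list's adjusted p in camera was 0.673. That setting also missed a simulated shift of 0.8 in this list (adjusted p = 0.219), so its missing call decides nothing. Fry did not call the list either, with an adjusted p of 0.536 as deposited and 0.306 with the trend removed. It was not run on simulated data, so whether it could find such a shift is not known.

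Genes of the colon epithelium such as EPCAM were near 0 in all 4 libraries labelled LoVo. Failed estimates listed as 0 are argued against, since 0 of 102 ribosomal protein and oxidative phosphorylation genes were at 0 in any library. RNA from cells other than epithelial colon cells stays open: 0 of the 6 genes EPCAM, CDH1, CDH17, VIL1, CDX2 and CEACAM5 reached 1 FPKM in any library, but they were picked because they were low, so that count decides nothing. Lists fixed beforehand, counted after the values were seen, do not rest on that pick. In them 4 of 34 enterocyte, 2 of 31 goblet and enteroendocrine and 14 of 29 epithelial junction genes reached 1 FPKM in all 4 libraries. A LoVo culture that has lost such genes stays open as well, and no other colon culture was compared.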

How the results depend on the processing

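The trend removal, the scalings, the filter of 5 FPKM, the weights, the hairpin fits at a pseudocount of 0.1 and every combination with the trend removal were tests chosen only after the result was seen; the others were planned. Median-of-ratios and upper quartile scaling in a count model, a negative binomial test, voom and a filter on scaled counts (CPM) were planned and not run, because the files hold FPKM. Depth is unknown, so no limit from depth can be given. Leaving out 1 library leaves 1 residual degree of freedom and assumes that the lone library varies like the other group.

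For knockdown against control, 0 genes rose and 0 fell as deposited, and also with upper quartile scaling, without a filter, at a pseudocount of 0.1 and at a minimum of 2-fold. Counts were 1 and 0 with median-of-ratios scaling and with the 5 FPKM filter (STC1 each), 1 and 1 with quantile normalization (STC1, LAMB3), 10 and 2 with the trend removed, 7 and 1 with symbols matched directly alone, 5 and 1 with library weights, which were 0.292 for each control and 3.42 for each shLAMB3 library, and 0 and 1 with the trend removed and control 1 left out. Leaving out 1 library gave 0 to 2883 rises and 0 to 1741 falls, the high counts without control 2; the cause was not tested. LAMB3 was called at -2.39 with quantile normalization, -2.41 with the trend removed in either matching, -2.53 with library weights, and ran from -2.81 to -2.24 with libraries left out.

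With the replicate block, 19 genes rose and 6 fell; with the trend removed as well, 7 rose and 1 fell, or 20 and 1 with symbols matched directly alone. In these 3 fits LAMB3 was at -2.53, -2.41 and -2.41, and the ERK and immediate-early list had an adjusted p of 0.0565 without trend removal. The block leaves 1 residual degree of freedom, so the spread used for a gene was largely that shared by genes of like level. As deposited the SE of LAMB3 was larger with the block (0.45 against 0.35), though its adjusted p was lower. Same-numbered libraries share only a number: their deviations correlated across genes with 0.0147, and with 0.0112 after the trend was removed.

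With the trend removed genes called were 60 higher and 45 lower for hairpin 1, 127 and 53 for hairpin 2, and 27 and 24 between hairpins (59 and 44, 127 and 53, 25 and 24 with symbols matched directly alone). Without a filter they were 0 for each, with quantile normalization hairpin 2 had 2 higher (STC1, NDRG1), with median-of-ratios scaling 0 genes were lower between hairpins, and at a pseudocount of 0.1 hairpin 1 had 1 lower (PLA2G4B) and 2 genes were lower between hairpins (IL11, KISS1). PLA2G4B and KISS1 were chosen after their values were seen. The hairpin correlation of 0.746 moved to 0.605 with the trend removed and from 0.551 to 0.912 with a control left out.

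Hypoxia and FOXO lists lost their calls with an estimated correlation (0.673) and fry (0.536). The estimated correlation in camera also missed a simulated shift of 0.8 in the hypoxia list (adjusted p = 0.219), and fry was not run on simulated data. DNA replication lost its call with quantile normalization (0.203), the 5 FPKM filter (0.0553), an estimated correlation (0.673) and fry (0.69), with 1.26e-05 to 0.433 over libraries left out. Mitosis lost it with quantile normalization (0.23), an estimated correlation (0.673) and fry (0.767), with 7.56e-18 to 0.986 over libraries left out. Oxidative phosphorylation turned upward with quantile normalization (0.676), with control 1 left out and the trend removed (0.585) and without control 1 (0.0787, of 2.64e-05 to 0.0787 over libraries left out), and ribosomal proteins without control 1 (0.568, of 1.43e-14 to 0.568). Beyond what the construction of a setting shows, the cause was not tested. Among the other results, mostly named genes and lists, those that kept direction and side of the threshold were, of 168, 167 with upper quartile scaling, 166 at a pseudocount of 0.1, 156 without a filter, 153 with quantile normalization and 142 with the trend removed (14 gained a call, 2 lost it, 10 changed otherwise). Median-of-ratios scaling kept 164 of 167. Since 0 genes passed for knockdown against control as deposited, keeping its side meant staying uncalled for a gene named in that comparison. These counts therefore do not measure how stable the called results were. Of 165, 158 were kept with weights, 149 with the block, 137 without control 1, 45 without control 2 (112 gained a call), 156 without hairpin 1 and 147 without hairpin 2.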

Other observations

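The levels in this part were picked only after the values were seen, and no test was run on them.

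Genes known from mesenchymal cells went both ways in level in the libraries labelled LoVo. AXL, a receptor kinase gene, measured 83.6 to 149 FPKM, CAV1 87.8 to 136, LGALS1 2060 to 4380 and ZEB1, a repressor of epithelial genes, 1.73 to 6.36, while COL1A1 measured 0.556 to 1.08, ACTA2 0.372 to 1.07 and TAGLN 0.702 to 2.36. NKX2-1, a transcription factor gene of lung and thyroid, measured 9.89 to 14.3 FPKM in the 4 libraries. The intestinal stem cell genes LGR5 and AXIN2 measured 0.0397 to 0.128 and 0.575 to 1.22. Of the 34 enterocyte differentiation genes, a list fixed before the data were examined, 4 reached 1 FPKM in all 4 libraries. KRT19 measured 45.0 to 101.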
